A study of Mus musculus with 16 samples.

How the data were processed

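The samples were 16 two-colour arrays of tail DNA from 8 mice, each hybridised against DNA of the same reference male in both dye orientations. Per the labels' protocols, DNA was extracted with a Kurabo PI-50a procedure and labelled by an Agilent protocol for oligonucleotide array CGH. Per the file headers, the arrays were Agilent design 024764, read with Feature Extraction 12.1.0.3 on the mm9 build. The deposited scanner files hold, per spot, processed intensity, median intensity and background intensity in each channel, and a log10 ratio of red over green. Per the file headers, the processed signals were background-subtracted and dye-normalised by a linear factor, with no lowess step. The authors also deposited a table of log2 values per array. Set against the scanner values, that table's slope was positive in 8 arrays and negative in 8, with correlations of 0.98 to 0.998 in size. It thus ran as reference over mouse in all 16, and its column medians lay between -0.0073 and 0.0151.

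Which dye held the mouse was taken from the labels. Each log10 ratio was converted to log2 of mouse over reference, spots with outlier flags were left out (120 to 539 per array), repeated spots of a probe were averaged and each array was centred on its autosomal median. No loess or quantile step was applied. The 2 arrays of a mouse were then averaged as 1 replicate. No spot was saturated (0 on every array), and 90 to 1979 spots per array were not well above background in some channel. The spread of the log ratio between neighbouring probes, as the scanner software reports it, was 0.156 to 0.216. Arrays of offspring 5 and 6 were the brightest, with Cy3 medians of 142.1 to 211.4 against 96.3 to 136.7 on the others. The arrays were scanned on 4 days with 2 mice each: father with mother, offspring 1 with 2, 3 with 4, and 5 with 6.

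Regions were called per mouse by an interval score, the mean log2 ratio times the square root of the number of probes, divided by the robust SD of that mouse. A call needed a score of at least 6, at least 3 consecutive probes, at most 200, and a mean of at least 0.25 in size and of 1 sign on both arrays. Calls of different mice that shared a probe and a sign were merged. A mouse carried a region when both arrays reached 0.25 with the sign of the region. An offspring-only region was carried by an offspring and by neither parent, and the offspring differed from each parent by at least 0.25 on both arrays. The background was the unturned dye pair: without turning the swapped array the signal of the mouse cancels, after removal of the mean dye bias of each probe in the other 7 mice. Dye bias particular to a mouse or scan day stays in this background but cancels in the turned pair. The background may therefore be too high. Differences between mouse and reference DNA other than copy number, such as DNA quality, stay in the turned pair and cancel in the background. For these the background may be too low, and an excess over it need not be copy number. Counts were compared with this background by exact sign-flip permutation tests, two-sided, over mice. These tests flip mice independently and do not allow for shared scan days. The 68 probes of X, 23 of Y and 36 of unplaced contigs were kept out of region counts and probe tests, a choice made after the data were seen.

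Single probes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the mouse means and group means for father, mother and offspring, which left 5 residual degrees of freedom and a prior of 4.8. The mean of all 8 mice was tested against 0 in a second fit. A probe passed at a Benjamini-Hochberg adjusted p under 0.05 and a log2 difference of at least 0.25. Block correlations came from 20000 probes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used otherwise.

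Both procedures were tested on simulated data. Of regions added to the unturned pairs over 950622 probes, 200 per mouse, all 160 losses of -1 with 3 probes were recovered, and 99.4% of the gains of 0.585 with 3 probes. In limma on 948494 simulated probes, 200 changed by 0.585 were recovered at 41.0% for offspring against parents, 1.5% for mother against father and 98.0% for all mice against the reference. For changes of 2, the shares were 98.0%, 91.0% and 100.0%. False calls numbered 24, 10 and 12.

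The tests, the alternatives and the rule for naming regions were fixed before the data were examined. The rule took the 10 offspring-only regions with the highest score, the 10 with the highest score among other regions not carried by all mice, and up to 10 carried by all 8. As labelled no region was carried by all 8 mice. Regions of at least 10 probes and those called in exactly the mother, offspring 5 and offspring 6 were added after the data were seen. For probes, the rule named the 5 largest past the threshold, of which there were none. Alternatives were normexp with an offset of 50, the authors' log2 table, no centring, a running-median wave correction, no dim probes, other thresholds and each mouse left out. Normexp was run on median signals in place of mean signals. Added later were the sign of offspring 4, alone and together with normexp, the omission of dim probes or a size of 0.4, a minimum of 10 probes and scan day as a block. Gene names and the planned test of multigene families were left out, since the gene table at hand belongs to another build, GRCm38.p6, and the columns of the scanner files used here give positions and no genes. Secondary screening arrays and TaqMan assays were not analysed here.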

Results

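DNA copy number was measured in 1 family of C57BL/6JNrs mice, an inbred black mouse line, by array comparative genomic hybridisation. The family held 1 father, 1 mother and 6 offspring. Tail DNA of each mouse, taken after death, was hybridised together with DNA of the same reference male from the colony. Each mouse was measured on 2 arrays with the dyes exchanged, and the pair counted as 1 replicate, so that 16 arrays gave 8 mice. The study was a first screen for copy-number aberrations in the progeny of males kept under continuous gamma-rays at 0.05 mGy per day for 400 days. The series title names exposed males, whereas its design text calls the father of this family non-irradiated. With 1 family and this contradiction, no comparison of exposed with unexposed fathers was made. The arrays carried 950622 different autosomal probes at a median distance of 2053 bp, in the mm9 mouse genome build. The median background-subtracted signal ran from 96.3 to 211.4 in Cy3 and from 115.1 to 248.2 in Cy5. The number of mice and arrays limits the precision of all values.

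Chromosomes X and Y served as a check of direction and scale. The median log2 ratio of mouse over reference male on 68 chromosome X probes was 0.95 in the mother, 0.98 in offspring 5 and 0.93 in offspring 6. It lay between 0.01 and 0.03 in the father and in offspring 1, 2, 3 and 4. On 23 chromosome Y probes the medians were -2.37 in the mother, -3.07 in offspring 5 and -2.25 in offspring 6, and between -0.04 and 0.05 in the other 5 mice. These values fix the direction of the ratio in the mother and in offspring 5 and 6. They cannot do so in a mouse whose X and Y values equal those of the reference.

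**Figure D1:**
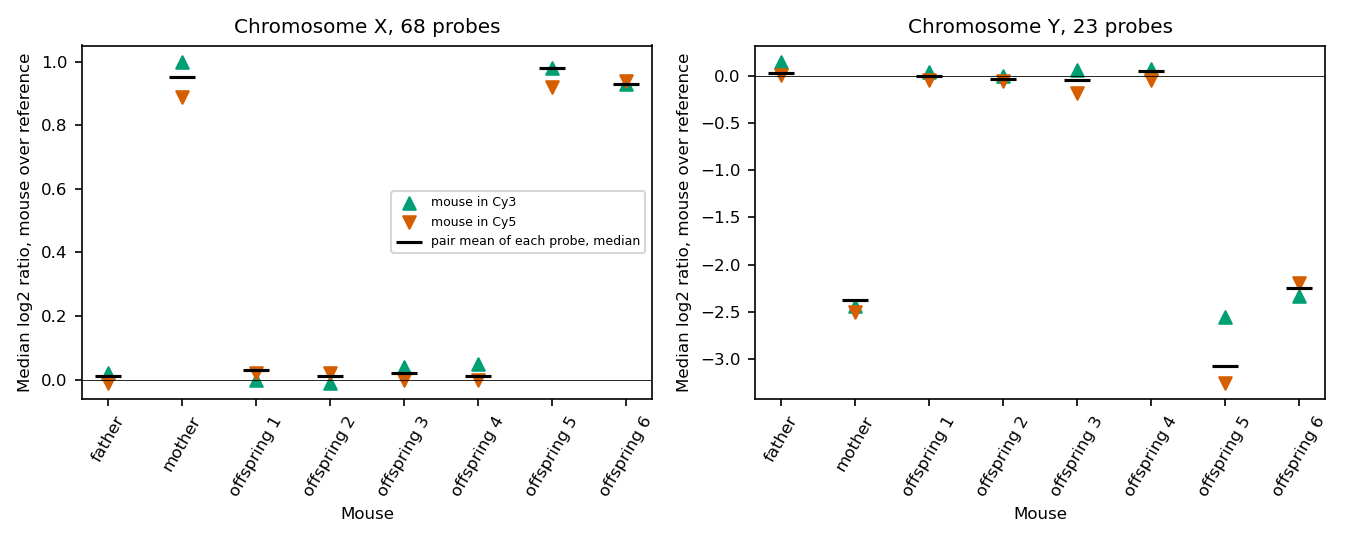
Median log2 ratio of mouse over reference male on chromosome X (left) and chromosome Y (right), per mouse. Triangles are the 2 arrays of a mouse and the bar is the median over probes of the pair mean; the mother, offspring 5 and offspring 6 lie between 0.93 and 0.98 on X and between -3.07 and -2.25 on Y.

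Offspring 4 ran against the other mice. Over all autosomal probes, its pair mean correlated with the mean of the other 7 mice at r = -0.364, against 0.294 in the father, 0.248 in the mother, 0.243 in offspring 1, 0.232 in offspring 2, 0.320 in offspring 3, -0.033 in offspring 5 and 0.205 in offspring 6. These correlations are across probes, which are not independent replicates. Single arrays of offspring 4 correlated at 0.19 to 0.44 with arrays of the same dye orientation. Its pair mean correlated at -0.27 to 0.08 with the pair means of single other mice. The positive array values thus come largely from a part that cancels in the pair mean, as a shared dye bias does. They do not show that its labels are right. In 11 of the 14 pairs of single arrays the value lay below the median correlation of that array with the remaining mice. That median ran from 0.33 to 0.45. The 3 above it were with offspring 5 in both orientations and offspring 6 in 1. The negative pair-mean correlation argues against the direction of the library labelled offspring 4. Its X and Y values cannot fix that direction, so it is not treated as settled. The main comparisons that use it are given below as labelled and with its sign turned, a step chosen after the data were seen. Others are given as labelled only. Among them are the counts of long regions, the merged count with normexp and the counts over trios of mice. The counts with a mouse left out and some limma settings were also run as labelled only.

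Which parts of the autosomes differed in copy number from the reference male, and in which mice, was the first question. A gain on chromosome 4 from 101110482 to 101270535, 160.1 kb with 74 probes, was present in the father at 0.56 (0.54 and 0.58 on the 2 arrays) and in offspring 2 at 0.55 (0.53 and 0.57). The other 6 mice lay between -0.02 and 0.01 there. In theory, 3 copies against 2 give 0.585. A loss on chromosome 13 from 100997510 to 101077537, 80.0 kb with 22 probes, was present in the mother at -0.32 and in offspring 1, 2, 3 and 5 at -0.36, -0.34, -0.36 and -0.40. The father, at 0.01, and offspring 4 and 6, at 0.03 and -0.03, lacked it. The loss was uneven along the region. The mother read -0.204 at its first probe and -0.711 at the probe from 101073472.

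On chromosome 10 from 33897213 to 33933441, 36.2 kb with 19 probes, 7 mice lay between -0.52 and -0.60, with a mean of -0.56 ± 0.02 (SD, n = 7). The library labelled offspring 4 read 0.56 there, and -0.56 with its sign turned. Chromosome 14 showed the same arrangement from 53385238 to 54386805, 1001.6 kb with 111 probes. The 7 mice lay between -0.20 and -0.28, with a mean of -0.23 ± 0.03 (SD, n = 7), and the library labelled offspring 4 read 0.24, or -0.24 with its sign turned. The chromosome 14 loss was called in these 7 mice. Over the whole of it, only offspring 6 met the rule for carrying it, at least 0.25 on both arrays. The gain called on chromosome 14 in offspring 4 ran from 53428774 to 54282483, with 86 probes at 0.26. Gain calls of the father and offspring 1 were merged into it, though they read -0.21 and -0.24 over the whole of it.

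**Figure D2:**
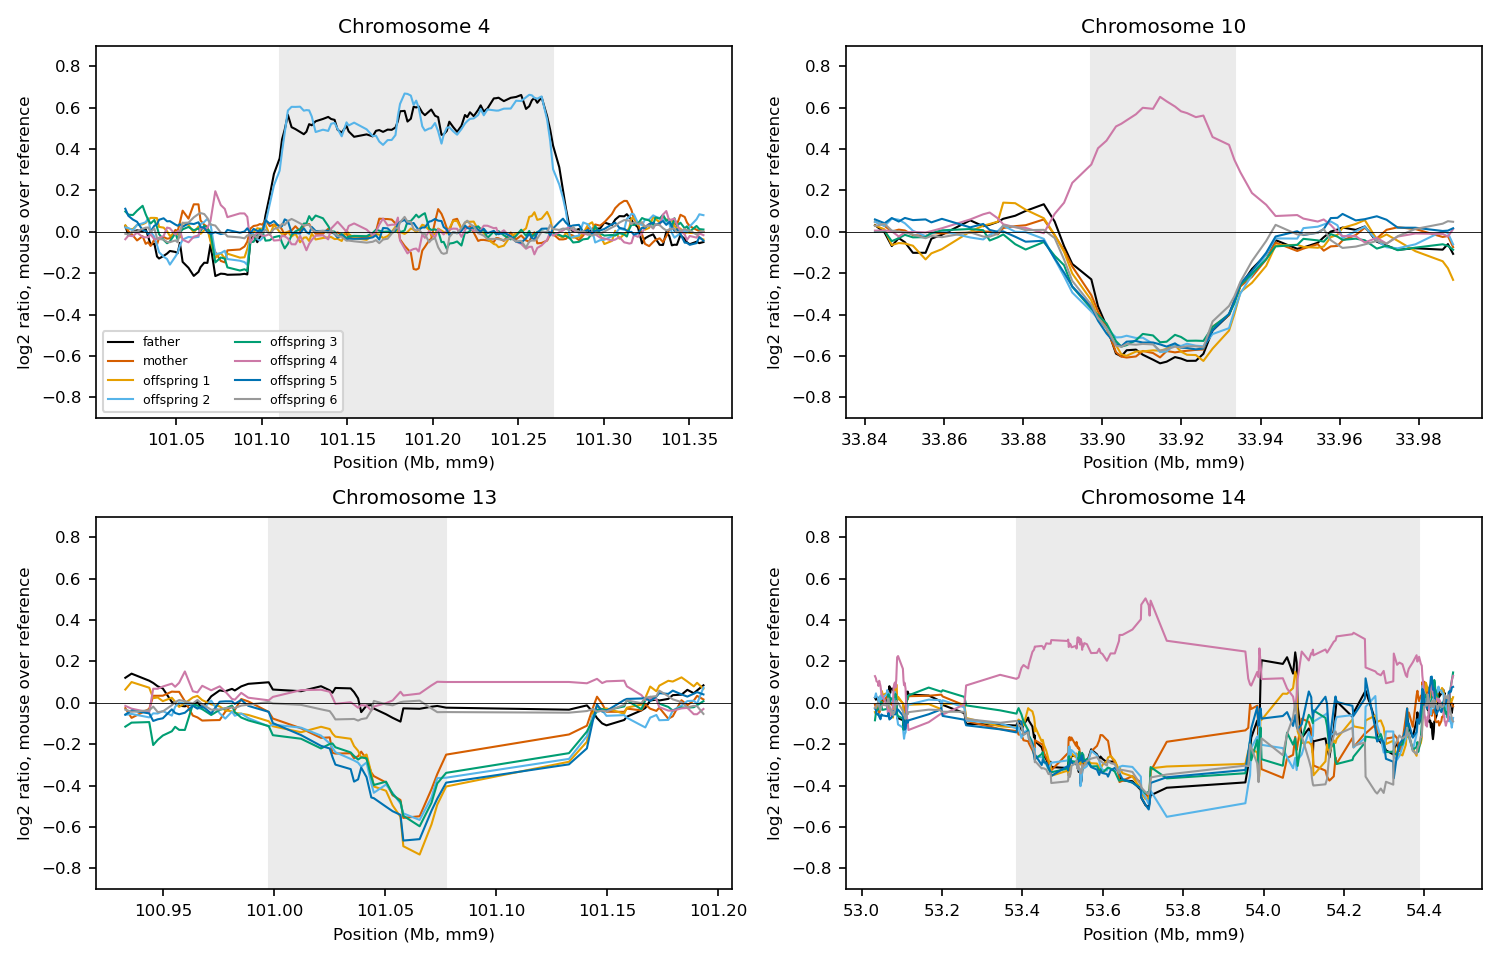
Log2 ratio of mouse over reference male along chromosomes 4, 10, 13 and 14 (mm9), as a running mean of 7 probes, with 1 line per mouse and the called region shaded. The father and offspring 2 stand at 0.56 and 0.55 on chromosome 4, and offspring 4 as labelled stands opposite to the other 7 mice on chromosomes 10 and 14.

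Several short regions separated the mother, offspring 5 and offspring 6 from the other 5 mice. The deepest lay on chromosome 3 from 25417435 to 25432738, with 3 probes, at -1.50 in the mother, -1.66 in offspring 5 and -1.65 in offspring 6. The other 5 mice lay between -0.03 and 0.04. Losses in the same 3 mice lay on chromosome 9 from 35853071 to 35865189, at -0.48, -0.42 and -0.53, and on chromosome 11 from 112955152 to 112961441, at -0.67, -0.71 and -0.69. On chromosome 5 from 123592752 to 123598838 the values were -0.70, -0.67 and -0.65. Shallower losses called in these mice lay on chromosome 5 from 109219280 to 109223996, on chromosome 6 from 104236953 to 104246570 and on chromosome 14 from 61798066 to 61804726. Chromosome 8 held the reverse, a gain from 102136827 to 102244157, 107.3 kb with 38 probes, at 0.25 in the mother, 0.23 in offspring 5 and 0.26 in offspring 6. The other 5 mice lay between -0.04 and 0.03 on chromosome 8. No mouse met the rule for carrying this gain, at least 0.25 on both arrays.

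Of the 10 highest-scoring regions outside the offspring-only class, 3 more rested on 3 probes. On chromosome 1 from 178991541 to 178996609 the father read -0.90, offspring 3 -0.57 and offspring 5 -1.33, while offspring 1 read 0.76, and the 2 arrays of the father differed, at -2.11 and 0.32. The mean of its carriers, -0.95, became -0.10 with normexp, a setting that replaced both the signals and their background correction, and -0.15 without dim probes. The gain on chromosome 7 from 113663718 to 113686608 was called in the mother alone, at 1.08, and became 0.08 and 0.22 in these settings. The gain on chromosome 12 from 16966191 to 16972042 was 1.05 in the father, on arrays at 0.30 and 1.80, while offspring 3 read 0.82, offspring 5 0.77 and offspring 2 -0.93. The value of the father became 0.30 and 0.15. Chromosomes as a whole stayed level, the largest chromosome median being 0.011, on chromosome 16 in offspring 2. A loss of 10 probes on chromosome 3 from 134162658 to 134182050 read -0.18 in the father and -0.29 in offspring 2, and no mouse met the rule for carrying it.

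In all, 2798 regions were called over the 8 mice, 688 gains and 2110 losses, and 78.8% of them held the minimum of 3 probes. The unturned dye pair, in which the signal of the mouse cancels, gave 752 calls by the same procedure. Differences of the DNA other than copy number cancel there too, so an excess over this background need not be copy number. The father had 785 calls against 127 in the unturned pair, offspring 2 726 against 98, offspring 4 464 against 78, offspring 3 344 against 80, the mother 234 against 99 and offspring 1 164 against 117. Offspring 5, with 44 against 69, and offspring 6, with 37 against 84, fell below that background. Over the 8 mice the difference gave p = 0.0469 in an exact sign-flip permutation test, two-sided, where 0.0078 is the smallest p possible. Offspring 5 and 6 shared a scan day. The test flips mice independently, so it does not allow for scan day. Losses made up 729 of the calls in the father and 711 in offspring 2, while gains made up 429 in the library labelled offspring 4. With the sign of offspring 4 turned, the 8 mice had 294 gains and 2504 losses.

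**Figure D3:**
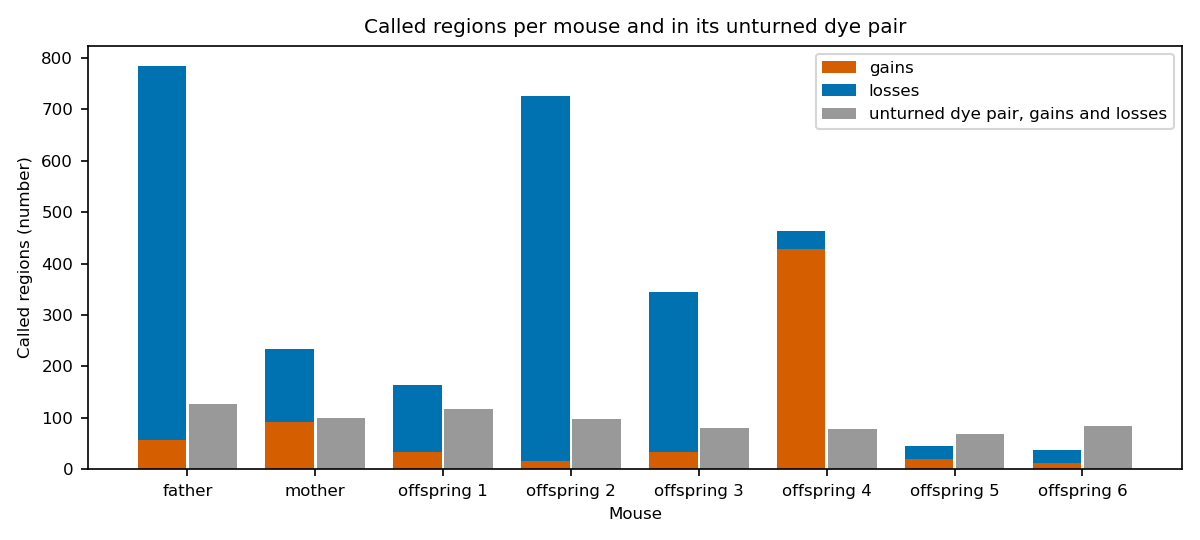
Number of called regions per mouse, gains and losses stacked, beside the number called in the unturned dye pair of the same mouse (grey). The father, with 785, and offspring 2, with 726, have the most calls, and offspring 5 and 6 have fewer than their unturned pairs.

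Merging calls of different mice gave 2194 regions, 666 gains and 1528 losses, of which 1800 were called in 1 mouse. The unturned pairs gave 665. A parent and an offspring both carried 410 regions, against 24 in the unturned pairs, and a parent alone carried 544, against 183. With the sign of offspring 4 turned, merging gave 1939 regions, 278 gains and 1661 losses, 439 of them in a parent and an offspring and 515 in a parent alone. Those that missed the offspring-only difference then numbered 737, and 107 had no carrier. Of the 2194 regions, as labelled, 9 held at least 10 probes, and none of the 665 did, the longest having 8. Called with a minimum of 10 probes, there were 32 against 3. Both the 9 and the 32 list the chromosome 10 and 14 loci as a gain and as a loss, through offspring 4 as labelled. They were not counted with its sign turned. With normexp on median signals there were 533 merged regions against 11, counted as labelled only.

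Copy-number changes present in offspring and absent from both parents were the aim of the screen. On chromosome 3 from 40573552 to 40593979, 20.4 kb with 11 probes, offspring 1 read 0.27 on the pair, with 0.26 and 0.27 on its arrays, and the other 7 mice lay between -0.03 and 0.02. This region was carried by offspring 1 alone but missed the required difference of 0.25 from each parent on both arrays. With normexp it was 0.08. It was singled out for its length after its values were seen. On chromosome 1 from 66758865 to 66768301, 6 probes read -0.58 in offspring 2, against 0.11 in the father and 0.07 in the mother, and -0.25 with normexp.

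The other offspring-only regions with high scores as labelled fell mostly to offspring 4. Besides the chromosome 10 and 14 regions, it read 0.81 on chromosome 2 from 160809442 to 160815526, 1.01 on chromosome 6 from 147610858 to 147614039 and 0.78 on chromosome 12 from 3628228 to 3632881, with 3 probes each. With normexp these were 0.42, 0.67 and 0.16, and the chromosome 12 value was 0.17 without dim probes. Its arrays differed widely, from 0.49 to 1.53 on chromosome 6. Offspring 3 read -0.80 on chromosome 3 from 135378985 to 135383715, which became -0.08 with normexp and -0.46 without dim probes. Offspring 2 read -0.79 on chromosome 14 from 97409451 to 97416903, and -0.26 with normexp. Offspring 5 read 0.70 on chromosome 6 from 120560871 to 120565281, which became -0.07 and -0.06 in the 2 settings. It read 0.72 on chromosome 14 from 107230301 to 107233262, and 0.26 with normexp. With the sign of offspring 4 turned, the chromosome 10 and 14 regions left this class, and chromosome 10 was then carried by all 8 mice at -0.52 to -0.60. Of the 10 highest-scoring offspring-only regions in that case, offspring 4 alone carried 3, at -0.81 on chromosome 2 from 160809442, -0.76 on chromosome 13 from 33048205 and -0.66 on chromosome 1 from 170432578. Another, on chromosome 5 from 12112952, was carried by 3 mice and called in offspring 1 at -0.82 and offspring 4 at -0.67, with offspring 2 at -0.34 and the mother at 0.69.

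As labelled, 490 regions were offspring-only, 386 gains and 104 losses, against 183 in the unturned pairs. The library labelled offspring 4 carried 372 of them, against 29. The others carried 35 against 48 (offspring 1), 68 against 43 (offspring 2), 15 against 35 (offspring 3), 7 against 16 (offspring 5) and 2 against 16 (offspring 6). The mean per offspring was 83.2 ± 143.5 (SD, n = 6) against 31.2 ± 13.4, a difference within the spread, with p = 0.7812 in an exact sign-flip permutation test, two-sided, where 0.0312 is the smallest p possible. With the sign of offspring 4 turned, 141 regions were offspring-only, 30 gains and 111 losses, against 189 in the unturned pairs, and without offspring 4 the count was 118. Offspring 4 then carried 30, against 35. The turned count gave 25.3 ± 24.8 per offspring (SD, n = 6) against 32.3 ± 13.5, with p = 0.3438 in the same exact permutation test. With normexp 121 regions were offspring-only against 4, without dim probes 384 against 70, and at a minimum size of 0.4 92 against 28. Offspring 4 as labelled carried 120, 331 and 83 of these, and in the exact permutation tests 48, 40 and 62 of the 64 sign flips were as extreme. With its sign turned the counts were 1 against 3, 68 against 69 and 11 against 28, with p = 0.75, 0.9062 and 0.0938 in the same exact tests. A test over 6 offspring cannot detect an excess confined to 1 of them. The unturned background may also be too high, so counts at or below it do not exclude such changes.

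Whether single probes differed between the generations was tested with limma on 948494 probes. None passed an adjusted p of 0.05 with a log2 difference of 0.25, and the smallest adjusted p was 0.447. At an unadjusted p of 0.05, 55194 probes passed. The count was again 0 with the sign of offspring 4 turned. Without the mother, the father alone stood for the parents, and only the offspring supplied the spread, as in the main fit. The probes that then stood out lay on chromosome 6 at 13573260 to 13573319 (-1.63) and chromosome 8 at 117157091 to 117157150 (1.30). Another lay on chromosome 13 at 102653453 to 102653512 (1.06). The 2 parents were scanned on a day of their own, so generation and scan day cannot be told apart. A random block for scan day left the count at 0.

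Between mother and father, measured on 1 scan day, no probe passed in limma, with a smallest adjusted p of 0.119 and 54161 probes at an unadjusted p of 0.05. Each parent is a single mouse assumed to vary like the offspring, so the long regions above, such as the chromosome 4 gain of the father (0.56 against -0.01) and the chromosome 13 loss of the mother (-0.32 against 0.01), were not resolved probe by probe. The count was also 0 with the sign of offspring 4 turned. Each parent is 1 mouse, and the estimated correlation within a mouse was 0.01, so the next fit counts the arrays of a mouse almost as independent. Over the 16 arrays with a dye term and the mouse as a block, 1 probe passed, on chromosome 8 at 109482026 to 109482085, higher in the mother by 1.36 (limma adjusted p = 0.0122). With normexp 7 probes passed, all higher in the mother, the largest on chromosome 6 at 113091422 to 113091481 (1.52).

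Probes at which the whole family differed from the reference male depended on offspring 4. As labelled, none passed in limma, with a smallest adjusted p of 0.593 and 77742 probes at an unadjusted p of 0.05. Without offspring 4, 76 probes passed, 7 higher and 69 lower in the family. The chromosome 10 region held 19 of them and the chromosome 14 region 39. Of the 18 elsewhere, the largest was a probe on chromosome 12 at 95868420 to 95868479, at 0.73 ± 0.03 (SE) with an adjusted p of 3.45e-05. With the sign of offspring 4 turned, 4028 probes passed, 217 higher and 3811 lower, including 19 in the chromosome 10 region and 56 in the chromosome 14 region. Outside these regions the median log2 ratio of the passing probes was -0.36. The reference was 1 mouse, so its own spread is not measured.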

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

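The tests on offspring 4, on the mother with offspring 5 and 6, on loss size and on the reference were chosen after the results were seen; the test on brighter probes was written before its result. For the exchange of dye labels 3 tests were tried, and those on the correlation itself and on chromosomes 10 and 14 were set aside because they rest on the values that showed the pattern. The bounds for loss size and for the reference were also changed after their values were seen, which turned both from excluded to open. The verdicts on them below rest on the values and not on those bounds. Among the 6 offspring, 36 sets of values were screened for a mouse far from its nearest neighbour relative to the whole range, and 9 stood out. Chance gives about 1 in 20 only in sets not chosen by their values, whereas 7 of the 9 came from named regions, several picked for a lone offspring, with chromosomes 10 and 14 listed more than once. As labelled, offspring 4 stood apart with 429 gains and with 372 offspring-only regions, which become 35 and 30 with its sign turned. It also stood apart at 0.56 on chromosome 10, from 33897213 to 33933441, in the region listed both as a gain and as a loss, and at 0.24 and 0.26 in the overlapping chromosome 14 regions. Offspring 2 stood apart at 0.55 on chromosome 4, where only the father among the other 7 mice was as high (0.56). Offspring 1 stood apart at 0.27 on chromosome 3 from 40573552 to 40593979. Offspring 5 stood apart at 0.70 on chromosome 6 from 120560871 to 120565281, a value that fell to -0.06 without dim probes.

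The opposite run of offspring 4 was weighed first. Over 941298 probes outside called regions its correlation with the mean of the other 7 mice was -0.333, which argues against copy-number differences of this mouse, since these are confined to regions. A scan-day effect is argued against by offspring 3, scanned on the same day, which correlated at 0.294 with its other 7 mice there, and at 0.347 without offspring 4 among them. An exchange of the dye labels of the pair may account for it: over 43 regions carried by at least 4 other mice, without chromosomes 10 and 14, its slope on their mean was -1.29, in size within the range of the other 7 mice. That range, -0.21 in offspring 5 to 1.74 in offspring 2, is wide and the sign was known beforehand. The test is therefore weak and does not by itself decide whether such an exchange happened.

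The regions shared by the mother, offspring 5 and offspring 6 were weighed next. In 7 merged regions exactly these mice lay beyond 0.25 and the other 5 within 0.15, against at most 5 in any other of the 56 trios, which is consistent with probes that also bind sequence on a sex chromosome, as these mice have the high X and low Y values. By calls alone the trio had 8 regions, behind trios with 54, 16 and 11, so this rests on a criterion set afterwards. Passage from the mother is argued against for the chromosome 3 region, where offspring 5 and 6 averaged -1.65 with the father near 0, more than the loss of 1 of 2 copies gives. Of 14 other such regions of the mother with an offspring carrier, 6 (42.9%) went to exactly offspring 5 and 6. That share lies between the bounds set for and against such passage. With the chromosome 3 region, those in exactly offspring 5 and 6 lay on 6 chromosomes. These regions were selected for lying in exactly these 2 offspring, so their spread over chromosomes does not decide on passage from the mother. The trio was also picked for this pattern. For the regions other than that on chromosome 3, passage from the mother stays open.

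The 1435 losses under 10 probes in the father and offspring 2 were weighed last. Low signal as the whole cause is argued against: among the brighter probes the turned pairs gave 181 calls against 3 in the father and 122 against 4 in offspring 2, a ratio of at least 30.5. It may still contribute, as the probes in these losses of the father had a median brightness percentile of 27.3 and normexp, which also replaced the signals, left 213 calls in the father and 195 in offspring 2. Loss of 1 of 2 copies in the father, passed on, is argued against for these losses as a set. Their medians were -0.43 in the father and -0.44 in offspring 2, and 0.07% reached -0.8. In theory such a loss gives -1, and chromosome X read 0.93 to 0.98 in the mother and offspring 5 and 6. The scale of dimmer probes was not measured. Shallower losses passed on stay open. The chromosome 13 loss shared by the mother and offspring averaged -0.32 to -0.40, but it was uneven. Offspring 1 read -0.139 at its first probe and -1.015 at the probe from 101073472. Its mean therefore does not give the size of a loss passed on. A property of the reference DNA alone is argued against, since all mice met the same reference. Called losses numbered 729 in the father and 142 in the mother, scanned together. They numbered 711 in offspring 2 and 131 in offspring 1, also scanned together. Offspring 3 had 311, and offspring 4, of the same day, 35 as labelled or 429 with its sign turned. Offspring 5 had 25 and offspring 6 had 26, but their arrays had a scan day of their own and were the brightest. The contrast with these mice cannot be told apart from scan day or brightness. Medians over the short losses were -0.40 in the father, -0.41 in offspring 2, 0.07 in offspring 5 and -0.05 in offspring 6. A contribution of the reference stays open, with medians of -0.19 in the mother and in offspring 1 and -0.20 in offspring 3. DNA quality and base composition were not tested.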

How the results depend on the processing

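The scan-day block, the minimum of 10 probes and the turned sign of offspring 4, alone or with another setting, were chosen after the data were seen. Merged regions numbered 2194 and offspring-only regions 490 as reported, and both stayed within 1.5 times under the authors' log2 table, no centring, wave correction and omission of dim probes. The counts moved to 533 and 121 with normexp, 4627 and 942 at a score of 5, 408 and 100 at a score of 8, 765 and 115 with at least 5 probes, 662 and 92 at a size of 0.4, 3440 and 1183 on the pair mean alone, and 32 and 4 with at least 10 probes (3 and 1 in the unturned pairs). Offspring-only regions fell to 141 with the sign of offspring 4 turned, and then to 1 with normexp, 68 without dim probes and 11 at a size of 0.4. Leaving out each mouse gave 1720 to 2174 merged regions, the lowest without the father. Offspring-only regions then numbered 118 to 708, the lowest without offspring 4. Thresholds change these counts by construction; for normexp the cause was not tested.

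The limma counts of 0 became non-zero in some settings, and the cause was not tested. Offspring against parents stayed at 0 when an offspring was left out. Without a parent, the other parent is a single mouse, and that count is not read here. Mother against father gave 7 with normexp, 1 over 16 arrays with the mouse as a block, and 0 to 0 when an offspring was left out; it has no value without a parent. All mice against the reference gave 0 to 76 when a mouse was left out, the 76 without offspring 4, and 4028 with its sign turned. The scan-day block changed no count from 0.

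Of 27 named regions, 12 moved by over 1.5 times or turned with normexp, 6 without dim probes and 0 under the authors' table, no centring or wave correction. The chromosome 6 gain of offspring 5 reversed to -0.07 with normexp and -0.06 without dim probes. Turning offspring 4 reversed its gains, to -0.81 on chromosome 2, -1.01 on chromosome 6, -0.56 on chromosome 10, -0.78 on chromosome 12 and -0.26 on chromosome 14, by construction. The multigene family test and its alternatives were not run, because positions and gene names came from different builds. No paired analysis was possible because the parents are single mice and the groups share fewer than 2 replicate numbers.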

Other observations

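Carriers of the long regions differed between offspring. Of the 6 offspring, only offspring 2 carried both the chromosome 4 gain of the father (0.55) and the chromosome 13 loss of the mother (-0.34). Offspring 1, 3 and 5 carried the chromosome 13 loss alone of these, and offspring 6 carried neither, at -0.01 and -0.03. Offspring 4, at -0.02 and 0.03, also carried neither, whichever way its sign is turned.

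Over the short losses of the father and offspring 2, medians in the other mice were -0.20 in offspring 3, -0.19 in the mother, -0.19 in offspring 1, -0.05 in offspring 6, 0.07 in offspring 5 and 0.24 in the library labelled offspring 4, or -0.24 with its sign turned.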
